A study of Homo sapiens with 12 samples.

How the data were processed

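The study measured messenger RNA in CFPAC1 cells, an established human pancreatic ductal adenocarcinoma line. Clones were isolated after infection with a lentiviral CRISPR-Cas9 plasmid, per the labels' protocols. The 12 libraries fell into 4 groups of 3 by the sample titles: WT and MYRF-KO, and HNF1B-WT and HNF1B-KO. The series text describes the MYRF groups as 3 deleted and 3 wild-type clones, so those libraries stand for separate clones. The labels call each HNF1B library a clonal line too, and the names in the header of that count table carry a different number for each of the 3 libraries of a group, so those were also taken as separate clones. Libraries followed SMART-Seq2, per the labels' protocols: reverse transcription of poly-A RNA from an oligo(dT) primer with template switching, amplification, and fragmentation with the Tn5 transposase. This chemistry does not mark strand, so reads of overlapping antisense genes cannot be told apart, and it uses no molecular identifiers, so amplified copies of a molecule were counted as separate reads.

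The deposited values are raw read counts per gene, in 1 table for the MYRF groups and 1 for the HNF1B groups. The authors counted reads over exons summed by gene with featureCounts, for which the submitters' processing notes give version 0.6.1, and the HNF1B table's counting command gives featureCounts 1.6.1, the largest-overlap option and GENCODE 28 on hg38, per the file headers. The annotation release of the MYRF table and the aligner are not given in the sources used here. The MYRF table held 19402 entries and that of HNF1B held 27123, of which 18 and 24 were Y copies of pseudoautosomal genes with 0 counts and were left out. Gene symbols came from a supplied identifier table, which named 19259 of 19384 and 22180 of 27099 identifiers. The tables shared 19309 identifiers, but only 15.5% of these had the same summed exon length in both, so the annotations differed and levels were never compared between tables. In the HNF1B table the column names carried no number that matched a sample title, so its libraries are named A to C within a group.

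The authors also deposited a table of their MYRF comparison, with log2 fold changes, log2 average CPM, a likelihood ratio score, p-values and FDR, whose columns are those of edgeR's likelihood ratio test, per the file headers. The submitters' processing notes give edgeR 3.2.2. The direction of its fold changes is not stated in the file and was taken from its correlation across genes with the values computed here.

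Counts were analysed in R 4.3.3 with edgeR 4.0.16. Each experiment was fitted alone, with its own 3 controls and 3 knockouts. Genes were kept by filterByExpr with default settings, libraries were scaled by TMM factors, and the quasi-likelihood test (glmQLFit with robust estimation, glmQLFTest) gave log2 fold changes of knockout over control, standard errors (SE) and p-values, adjusted by the Benjamini-Hochberg method. Every adjusted p for a gene is from that test unless another tool is named. A gene was called when its adjusted p was under 0.05. The difference between the knockouts was tested as an interaction over all 12 libraries on shared identifiers, as the MYRF-KO response minus the HNF1B-KO response, each against its own controls. Overlaps of calls were compared with the product of the list sizes over the number of genes tested in both, with Fisher's exact test, two-sided. CPM values are TMM-scaled and given as mean ± SD. Where a group held 0 reads of a gene, the fold is a bound against 3 counts over the group. Where it held 1 to 3 reads, the ratio is given with an exact 95% counting interval. Both cover counting error only.

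Before the data were examined, 32 gene lists and the rule for named genes were fixed. The rule took a panel of 21 genes, the 8 genes with the largest changes in each direction among calls with an average log2 CPM of at least 4 and no overlap between groups, which chance gives for 10% of genes, and up to 3 rising and 3 falling members per list. For the overlap it took the genes with the largest smaller change at an average log2 CPM of at least 3, and for the interaction 5 per direction. Y-linked genes and XIST were left out. Each list was tested with camera (limma 3.58.1, two-sided) at a preset inter-gene correlation of 0.01, adjusted over the 32 lists, and again with an estimated correlation and with fry, which asks whether a list's genes move on balance one way without comparing them with other genes. Counts of list members are given over all genes and adjusted over the list alone.

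Alternatives fixed before the data were examined were RLE and upper-quartile factors, DESeq2 1.42.0, limma-voom, no low-count filter, a filter of 1 CPM in 3 libraries, a test against a 2-fold change (glmTreat), 1 dispersion shared by the 12 libraries, a replicate block, and leaving out each library. After the data were examined, the likelihood ratio test, a subtraction of the median shift of the 50 neighbouring expressed genes in each library, and a subtraction of each library's trend with exon length were added. The pipeline was tested on simulated data drawn from the real means and library sizes. It recovered 60.6% of genes changed 2-fold and 80.8% of those changed 4-fold in the MYRF design of 13439 genes, 19.6% and 76.8% in the HNF1B design of 15147 genes, and 11.0% and 58.2% in the interaction of 14384 genes. False calls numbered 8 of 148, 7 of 102 and 7 of 75. These simulations held 97 to 100 changed genes at each fold, and recovery after adjustment depends on that number. The regional subtraction took a simulated block shift from a median of 0.576 to 0.00111 in the MYRF design and from 0.542 to 0.00415 in the HNF1B design. That block was the expressed genes of a whole chromosome, shifted alike in every knockout library. Shifts in the data differed between libraries and some ended within a chromosome, and the subtraction was not simulated on such shifts.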

Results

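Messenger RNA was measured in CFPAC1, a human pancreatic ductal adenocarcinoma cell line, in 12 libraries from clones isolated after CRISPR-Cas9 infection. The WT and MYRF-KO groups held 3 libraries each, and so did the HNF1B-WT and HNF1B-KO groups, which form a separate experiment. Counts assigned to genes totalled 32.01 to 36.4 M in the WT libraries and 21.7 to 31.0 M in MYRF-KO, with 15326 to 15769 genes detected. The HNF1B-WT libraries held 17.2 to 27.4 M counts and the HNF1B-KO libraries 18.4 to 24.4 M, with 19251 to 21550 genes detected. The 10 most abundant genes took 6.09% to 7.03% of a library. Replicates of a group differed by far more than counting noise, with a chi-square of 16.4 to 129 per gene for a pair. Library HNF1B-KO C stood apart: its log2 CPM correlated across genes with HNF1B-KO A and B at 0.948 and 0.953, against 0.983 between those 2 libraries.

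MYRF, a membrane-bound transcription factor known as a regulator of myelin genes in glia, kept its transcript level in MYRF-KO, while HNF1B, a homeodomain transcription factor of ductal and liver cells, lost most of its transcript in HNF1B-KO. MYRF (ENSG00000124920, chromosome 11, 61752642 to 61788518, hg38) stood at 56.8 ± 13.9 CPM in WT and 61.4 ± 14.7 CPM in MYRF-KO (SD, n = 3 each). The log2 fold change was 0.11 (SE 0.23, edgeR adjusted p = 0.835), so the counts do not check the MYRF-KO labels, and an edit that changes the protein need not lower the transcript. HNF1B (ENSG00000275410, chromosome 17, 37686432 to 37745247) fell from 99.7 ± 5.50 CPM in HNF1B-WT to 8.29 ± 8.63 CPM in HNF1B-KO, a log2 fold change of -3.57 (SE 0.83, adjusted p = 0.0337). Its level was 0.847, 6.28 and 17.8 CPM in HNF1B-KO A, B and C, all below the 93.6 CPM of the lowest control. For HNF1B in HNF1B-KO the adjusted p was 0.0961 without HNF1B-WT A, 0.0823 without HNF1B-WT B, 0.0988 without HNF1B-WT C and 0.119 without HNF1B-KO B. The log2 fold change over all settings tried stayed between -4.81 and -3.04.

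MYRF itself fell in HNF1B-KO, from 38.9 ± 8.82 to 11.1 ± 2.12 CPM (log2 fold change -1.82, SE 0.23, adjusted p = 0.00626), and stayed lower with each library left out (-1.95 to -1.64). HNF1B did not change detectably in MYRF-KO, with 143 ± 14.6 CPM in WT and 146 ± 4.41 CPM in MYRF-KO (log2 fold change 0.04, SE 0.12, adjusted p = 0.901). TMEM98, a membrane protein known to bind MYRF and block its self-cleavage (chromosome 17, 32927910 to 32945106), rose in HNF1B-KO by 4.01 on the log2 scale (SE 0.80, adjusted p = 0.0221), with 152, 81.8 and 15.5 CPM in libraries A, B and C against 3.17 to 7.61 CPM in the controls. That call was lost without any single library except HNF1B-KO C (adjusted p = 0.0533 to 0.0932). In MYRF-KO its log2 fold change was 1.35 (SE 0.86, adjusted p = 0.450).

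**Figure D1:**
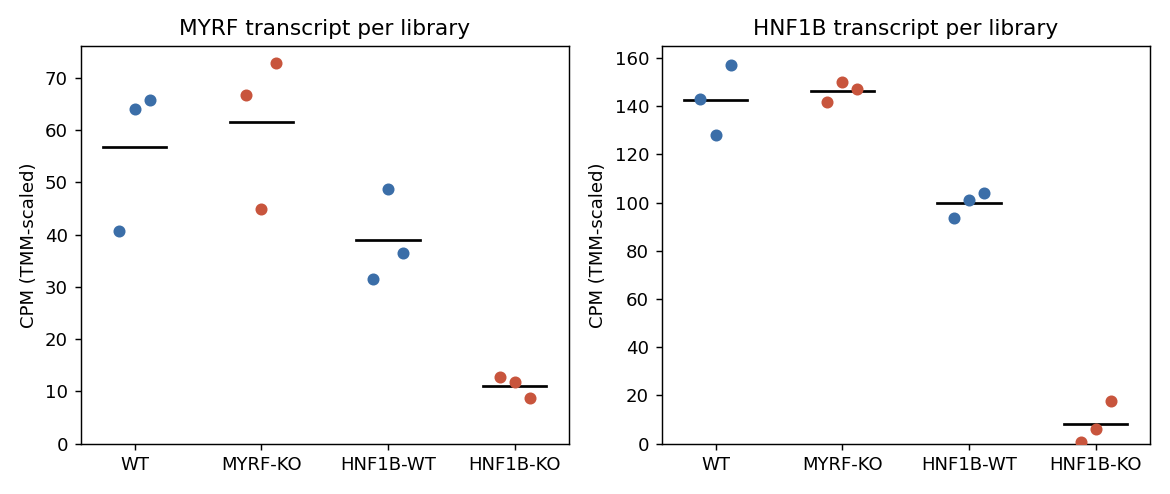
TMM-scaled CPM of MYRF and HNF1B in each of the 12 libraries, by group, with a black line at the group mean. HNF1B lies between 0.847 and 17.8 CPM in HNF1B-KO and between 93.6 and 104 CPM in HNF1B-WT, while MYRF overlaps between WT and MYRF-KO.

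The first comparison asked which transcripts differ between the clones labelled MYRF-KO and WT. The series title ties MYRF to homeostasis of the endoplasmic reticulum (ER). In MYRF-KO, CEMIP, a hyaluronan-binding protein needed for hyaluronan breakdown, rose from 9.86 ± 2.59 to 61.9 ± 18.1 CPM (SD, n = 3; log2 fold change 2.65, SE 0.27, edgeR adjusted p = 0.0283; ENSG00000103888, chromosome 15, 80779343 to 80951776). GPX2, a glutathione peroxidase of the gut epithelium, rose from 53.9 ± 10.9 to 178 ± 39.1 CPM (1.72, SE 0.21, adjusted p = 0.0379), and HERPUD1, an ER membrane protein of protein degradation that is induced by ER stress, from 149 ± 9.77 to 315 ± 54.4 CPM (1.08, SE 0.15, adjusted p = 0.0379; chromosome 16, 56932142 to 56944864). FOS, an immediate early transcription factor, fell from 923 ± 302 to 229 ± 13.8 CPM (-2.01, SE 0.22, adjusted p = 0.0353; chromosome 14, 75278826 to 75282230). PROM1, the surface glycoprotein CD133, fell from 704 ± 48.1 to 300 ± 43.3 CPM (-1.23, SE 0.15, adjusted p = 0.0379; -0.83, SE 0.20, adjusted p = 0.105 after the regional subtraction).

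Of 13570 genes tested, 69 passed edgeR's quasi-likelihood test, 45 higher and 24 lower, and 30 and 19 of these by at least 2-fold. Among the largest rises were CYP3A5, a drug-metabolising cytochrome P450 (2.10, SE 0.27, adjusted p = 0.0379), and G0S2, an inhibitor of fat breakdown (1.77, SE 0.26, adjusted p = 0.0439). PRSS3, a trypsinogen (1.6, SE 0.22, adjusted p = 0.0384), and KRT86, a keratin (1.62, SE 0.24, adjusted p = 0.0439), belong to families whose close copies could share reads. CYB5R2, a cytochrome b5 reductase, rose by 1.55 (SE 0.23, adjusted p = 0.0406) and PPTC7, a mitochondrial phosphatase, by 1.47 (SE 0.24, adjusted p = 0.0472). Among the largest falls were FBN2, a microfibril protein (-2.0, SE 0.26, adjusted p = 0.0379), MYLK, the myosin light chain kinase (-1.98, SE 0.24, adjusted p = 0.0379), and CCN2, a matricellular protein (-1.80, SE 0.25, adjusted p = 0.0427). LPCAT2, a lysophospholipid acyltransferase, fell by 1.15 (SE 0.11, adjusted p = 0.0216), ZNF488 by 1.38 (SE 0.22, adjusted p = 0.0439) and MXRA5 by 1.24 (SE 0.20, adjusted p = 0.0472). These calls were fragile: no gene passed without WT 1, WT 3 or MYRF-KO 3, 4 passed without WT 2 and 37 without MYRF-KO 2, whereas DESeq2 called 949. Without MYRF-KO 1, 98 passed, and the balance of directions turned over, with 38 higher and 60 lower.

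Neighbouring genes shifted together on chromosome 4 in MYRF-KO and, over long stretches of chromosome 1, in the MYRF-KO libraries and in WT 2. After the median shift of neighbouring genes was subtracted, 35 genes passed, 33 of them among the 69. Among the genes named here, the lost calls on chromosome 4 were PROM1 (-1.23 to -0.83, SE 0.20), SEC24D (0.92 to 0.75, SE 0.18), OSTC (0.78 to 0.54, SE 0.11) and AREG (1.42 to 1.14, SE 0.23). On chromosome 1 they were KRTCAP2 (0.82 to 0.58, SE 0.13), LAMB3 (1.22 to 1.02, SE 0.19) and G0S2 (1.77 to 1.57, SE 0.28), and on chromosome 8 CA2 (-1.01 to -0.93, SE 0.14). PPTC7 (1.47 to 1.55, SE 0.25) and SYVN1 (1.11 to 1.19, SE 0.24) lost the call with a larger fold and a larger SE, so the losses of these 2 genes give no evidence of a regional cause. For these 10 named genes the adjusted p after the subtraction lay between 0.0516 for CA2 and 0.105 for PROM1.

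Genes of the ER stress response stood higher in MYRF-KO as groups by camera at the preset correlation, though few members passed singly. Of 22 targets of IRE1-XBP1 signalling and ER-associated degradation, 2 rose and 0 fell over all genes, against 10 and 1 adjusted over the list alone, with a median log2 fold change of 0.32. They were SYVN1, a ubiquitin ligase of ER-associated degradation (1.11, SE 0.17, edgeR adjusted p = 0.0439), and SEC24D, a coat protein of ER exit vesicles (0.92, SE 0.15, adjusted p = 0.0439). After the regional subtraction neither SYVN1 (edgeR adjusted p = 0.0865, with a larger fold) nor SEC24D (adjusted p = 0.102) passed. Of 21 ER chaperones of the ATF6 type, 1 rose, HERPUD1, and 6 rose adjusted over the list alone, with a median of 0.17. HSPA5, the chaperone BiP, had a log2 fold change of 0.69 (SE 0.17, adjusted p = 0.0998) and did not pass. Of 26 genes of the ATF4-CHOP integrated stress response, 0 passed edgeR over all genes, 12 were higher and 0 lower adjusted over the list alone, and the median was 0.60. Among them DDIT3, the transcription factor CHOP, stood at 1.44 (SE 0.25, adjusted p = 0.0540), CHAC1, a glutathione-degrading enzyme, at 1.81 (adjusted p = 0.0678) and ATF4 at 0.59 (SE 0.16, adjusted p = 0.109). By camera these 3 lists were higher than other genes (adjusted p = 0.00437, 0.00437 and 3.87e-06), which was lost with an estimated correlation (adjusted p = 0.330 with an estimated correlation for the IRE1-XBP1 list, 0.432 for the ATF6 list and 0.378 for the ATF4-CHOP list). DDIT3, HSPA5, ATF4 and XBP1 (0.53, SE 0.13, adjusted p = 0.0990) passed with DESeq2 and with the likelihood ratio test.

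Lists for later steps of the secretory pathway held 3 calls in MYRF-KO, all in N-glycosylation. Of 33 genes of N-glycosylation, 3 rose over all genes and 3 adjusted over the list alone, all of the oligosaccharyltransferase complex: TUSC3 (1.53, SE 0.22, edgeR adjusted p = 0.0384), KRTCAP2 (0.82, SE 0.13, adjusted p = 0.0439) and OSTC (0.78, SE 0.13, adjusted p = 0.0472). After the regional subtraction TUSC3 stayed called (edgeR adjusted p = 0.0439), while KRTCAP2 (adjusted p = 0.095) and OSTC (adjusted p = 0.085) did not. The list as a whole did not pass camera (adjusted p = 0.596), and its median of -0.02 differed in sign from its mean of 0.11. Of 34 genes of COPII and COPI vesicle transport, 0 passed over all genes and 0 adjusted over the list alone, but the list, with a median of 0.17, was higher by camera (adjusted p = 0.00701; adjusted p = 0.408 with an estimated correlation). COPII and COPI vesicle transport in MYRF-KO had an adjusted p of 0.0720 without MYRF-KO 3. Of 21 genes of ER disulfide exchange, which include AGR2 (0.32, SE 0.15, adjusted p = 0.281), 0 passed over all genes and 0 rose and 2 fell adjusted over the list alone (median 0.02 with a mean of -0.03, camera adjusted p = 0.832). HSP90B1, an abundant ER chaperone, stood at 0.13 (SE 0.14, adjusted p = 0.665). None of 25 O-glycosylation enzymes passed the edgeR test, over all genes or adjusted over the list alone (median 0.02, camera adjusted p = 0.832).

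Genes for secreted and surface glycoproteins stood higher in MYRF-KO as groups by camera at the preset correlation. With fry the CEACAM and glycoprotein list passed (adjusted p = 0.0477) and the mucins and trefoil peptides did not (adjusted p = 0.0966). Of 21 genes of the CEACAM and glycoprotein list, 0 passed edgeR over all genes and 8 were higher and 0 lower adjusted over the list alone. Its members had a median of 0.82 (camera adjusted p = 0.000119; adjusted p = 0.30 with an estimated correlation). Among them CEACAM6, an adhesion glycoprotein, stood at 91.2 ± 18.9 CPM in WT and 560 ± 413 CPM in MYRF-KO (2.62, SE 0.58, adjusted p = 0.0998), its paralog CEACAM5 at a log2 fold change of 2.63 (SE 0.65, adjusted p = 0.116), and DMBT1, a mucin-like scavenger protein, at 4.66 (adjusted p = 0.0611). Of 14 mucins and trefoil peptides, 0 passed over all genes and 5 were higher and 0 lower adjusted over the list alone. Members had a median of 0.98 (camera adjusted p = 0.000542; adjusted p = 0.330 with an estimated correlation). MUC16 stood at 1.05 (adjusted p = 0.143) and MUC13 at 1.73 (adjusted p = 0.132), while MUC1 (0.09, SE 0.27, adjusted p = 0.888), MUC5AC (0.53, SE 0.53, adjusted p = 0.640) and MUC5B (1.89, SE 0.81, adjusted p = 0.251) gave no call either. Of 14 markers of the classical pancreatic cancer subtype, 4 of whose list is shared with the glycoprotein list, 0 passed over all genes and 3 were higher adjusted over the list alone (median 0.85, camera adjusted p = 0.000571; adjusted p = 0.330 with an estimated correlation). Of 22 markers of the basal-like subtype, 1 rose over all genes and 1 adjusted over the list alone, AREG, a ligand of the EGF receptor (1.42, SE 0.22, adjusted p = 0.0439; list median 0.35, camera adjusted p = 0.262).

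Cytosolic ribosomal protein genes were the list with the smallest camera p in MYRF-KO, all 38 of them above 0. None passed edgeR over all genes, 25 were higher and 0 lower adjusted over the list alone, and the median was 0.45 (camera adjusted p = 2.08e-14; adjusted p = 0.422 with an estimated correlation). RPS27 stood at 0.97 (adjusted p = 0.0720) and RPS8 at 0.73 (adjusted p = 0.0634). Of 30 cell cycle genes, 0 passed over all genes and 0 were higher and 11 lower adjusted over the list alone (median -0.31, camera adjusted p = 4.17e-07; adjusted p = 0.422 with an estimated correlation), among them the replication helicase genes MCM7 (-0.68, adjusted p = 0.0544) and MCM5 (-0.83, adjusted p = 0.0631). Of 28 NF-kB and inflammatory genes, 0 passed over all genes and 6 were higher and 0 lower adjusted over the list alone (median 0.62, camera adjusted p = 3.87e-06; adjusted p = 0.432 with an estimated correlation), among them BIRC3, an inhibitor of apoptosis (0.98, adjusted p = 0.109). Of 26 genes of hypoxia and glycolysis, 0 passed over all genes and 1 was higher and 6 lower adjusted over the list alone (median -0.38, camera adjusted p = 0.000571; adjusted p = 0.432 with an estimated correlation), among them PFKFB4, a regulator of glycolysis (-1.47, adjusted p = 0.0678). At the same threshold 69 of all 13570 genes tested passed, so 0 calls over all genes do not set these 4 lists apart. An unadjusted p under 0.05 was found for 2581 of the 13570 genes, which is the background for the counts adjusted over the list alone.

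A further 4 lists passed camera in MYRF-KO and lost that call without at least 2 of the single libraries. Of 33 interferon-stimulated genes, 0 passed edgeR over all genes or adjusted over the list alone, with a median of -0.20 (camera adjusted p = 0.00648; adjusted p = 0.727 with an estimated correlation). Interferon-stimulated genes in MYRF-KO had an adjusted p of 0.0909 without WT 3 and 0.0720 without MYRF-KO 3. Of 25 genes of the basement membrane and integrins, 1 rose over all genes and 1 adjusted over the list alone, LAMB3, a laminin chain (1.22, SE 0.20, adjusted p = 0.0449; list median 0.20, camera adjusted p = 0.0478; adjusted p = 0.432 with an estimated correlation). Basement membrane and integrins in MYRF-KO had an adjusted p of 0.247 without WT 1, 0.191 without MYRF-KO 1 and 0.0731 without MYRF-KO 3. Of 5 acinar markers, 1 rose over all genes and 1 adjusted over the list alone, PRSS3 (list median 0.47, camera adjusted p = 0.0362; adjusted p = 0.422 with an estimated correlation). Acinar cell markers in MYRF-KO had an adjusted p of 0.271 without WT 1, 0.0524 without WT 3 and 0.0731 without MYRF-KO 3. Of 6 leukocyte markers, 0 passed over all genes or adjusted over the list alone (median 0.70, camera adjusted p = 0.0381; adjusted p = 0.408 with an estimated correlation). Leukocyte markers in MYRF-KO had an adjusted p of 0.30 without WT 3 and 0.0720 without MYRF-KO 3.

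The remaining lists did not pass camera in MYRF-KO. Of 12 myelin genes regulated by MYRF in glia, 0 passed over all genes and 0 rose and 1 fell adjusted over the list alone (median -0.03, camera adjusted p = 0.832). Of 22 genes of duct ion transport and the cilium, 0 rose and 1 fell over all genes, CA2, a carbonic anhydrase (-1.01, SE 0.15, edgeR adjusted p = 0.0439), and 1 rose and 3 fell adjusted over the list alone (median -0.04, camera adjusted p = 0.363). Of 23 pancreatic and foregut transcription factors, 0 passed over all genes or adjusted over the list alone (median 0.07, camera adjusted p = 0.177), including HNF1A (-0.05), HNF4A (-0.11), FOXA2 (0.11) and GATA6 (0.83, adjusted p = 0.150). None of the 21 genes reported as HNF1 targets (median -0.03, camera adjusted p = 0.832), 25 epithelial genes (0.15, 0.102), 22 mesenchymal genes (-0.33, 0.107), 21 p53 targets (-0.03, 0.958), 27 lysosome genes (-0.13, 0.747), 13 mitochondrially encoded mRNAs (0.13, 0.177) or 8 fibroblast and endothelial markers (-0.27, 0.931) passed, over all genes or adjusted over the list alone. CDH1 (0.00, SE 0.17, adjusted p = 0.997) and VIM (-0.15, SE 0.26, adjusted p = 0.798), markers of epithelial and mesenchymal cells, were among them. Medians below 0 stood beside means above 0 for the HNF1 targets (0.22), p53 targets (0.07), lysosome genes (0.04), fibroblast and endothelial markers (0.10) and myelin genes (0.02). Of 24 cholesterol synthesis genes, 23 fatty acid synthesis genes and 9 endocrine markers, 0 passed over all genes and 2, 1 and 1 were lower adjusted over the list alone (medians -0.09, -0.14 and -0.11, camera adjusted p = 0.250, 0.250 and 0.262). CFTR, a chloride channel of duct cells, had 0 to 10 counts per library and was not tested.

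The authors' deposited table of the same comparison, made with a likelihood ratio test, listed 12197 genes, 700 of them with FDR under 0.05, 374 higher and 326 lower. Its log2 fold changes correlated across genes with those computed here at 0.999996, so the difference in number came from the test and not from the fold changes. Of the 69 genes called here, 67 were among the 700 and 2 were not in the table. The authors' deposited table gave DDIT3 an FDR of 2.70e-06, HSPA5 0.0370, ATF4 0.0353, HERPUD1 2.70e-06 and MYRF 0.864. XBP1, with an FDR of 0.0560, did not pass there.

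The second comparison asked which transcripts differ between the clones labelled HNF1B-KO and HNF1B-WT. In HNF1B-KO, TM4SF4, a tetraspanin-like membrane protein of liver and pancreas (ENSG00000169903, chromosome 3, 149473974 to 149503281), fell from 304 ± 90.7 to 0.106 ± 0.103 CPM (SD, n = 3; log2 fold change -11.27, SE 0.53, edgeR adjusted p = 0.000322). ONECUT2, a transcription factor of foregut development (ENSG00000119547, chromosome 18, 57435685 to 57491297), fell from 77.1 ± 7.19 to 0.757 ± 0.223 CPM (-6.65, SE 0.24, adjusted p = 9.38e-05), and HNF4A, a nuclear receptor of hepatic and intestinal cells (chromosome 20, 44355700 to 44434596), from 15 ± 4.01 to 0.610 ± 0.175 CPM (-4.59, SE 0.35, adjusted p = 0.00154). SLITRK6, a neuronal-type transmembrane protein (ENSG00000184564, chromosome 13, 85792787 to 85806683), rose from 0.208 ± 0.0632 to 32.8 ± 3.84 CPM (7.25, SE 0.27, adjusted p = 9.38e-05). KRT17, a keratin of basal epithelia, rose from 40.2 ± 6.25 to 299 ± 102 CPM (2.90, SE 0.27, adjusted p = 0.00273).

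Of 15417 genes tested, 2003 passed, 1070 higher and 933 lower, and 513 and 640 of these by at least 2-fold. With upper-quartile scaling, 41.3% of 1938 calls were higher, against 53.4% with the scaling used here. Other large falls were NNMT, nicotinamide N-methyltransferase, from 759 ± 277 to 4.88 ± 6.80 CPM (-7.24, SE 1.15, adjusted p = 0.0121), CP, the copper protein ceruloplasmin (-7.81, SE 0.68, adjusted p = 0.00221), CLDN2, a tight junction protein (-9.05, SE 1.26, adjusted p = 0.00863), SFTA2 (-7.41, SE 0.67, adjusted p = 0.00254) and SGK2, a kinase (-6.72, SE 0.41, adjusted p = 0.000770). HABP2, a secreted protease, had 0 counts in HNF1B-KO and 4606 in HNF1B-WT, at least 1275-fold lower against 3 counts over the group. Several of the largest rises were carried mainly by some libraries: KLK5, a secreted kallikrein protease, stood at 2008, 2328 and 2.55 CPM in HNF1B-KO A, B and C (10.21, SE 2.17, adjusted p = 0.0266), TH, tyrosine hydroxylase, at 27.8, 74.6 and 0.700 CPM (8.82, SE 1.83, adjusted p = 0.0249), and KRT13 at 38.9, 18.4 and 399 CPM (5.27, SE 1.21, adjusted p = 0.0333). KLK5 and TH lost the call without any single library except HNF1B-KO C, and KRT13 without each control. PRSS2, a trypsinogen with close copies, rose by 9.93 (SE 1.48, adjusted p = 0.00999), GASK1B by 4.98 (SE 0.85, adjusted p = 0.0145), MAB21L4 by 4.51 (SE 0.79, adjusted p = 0.0152) and BMP3, a bone morphogenetic protein, by 4.48 (SE 0.82, adjusted p = 0.0172). The number called was 376 without HNF1B-WT A, 977 without HNF1B-WT B, 436 without HNF1B-WT C, 801 without HNF1B-KO A, 524 without HNF1B-KO B and 4503 without HNF1B-KO C.

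HNF1 targets were the list with the lowest median in HNF1B-KO. Of 22 tested, 0 rose and 13 fell over all genes, against 1 and 17 adjusted over the list alone, with a median log2 fold change of -3.88, also with the gene at 0 counts set to its bound. By camera the list was lower (adjusted p = 9.95e-10; adjusted p = 0.247 with an estimated correlation). PKHD1, the polycystic kidney and hepatic disease protein fibrocystin, fell from 37.5 ± 7.38 to 0.491 ± 0.491 CPM (-6.30, SE 0.55, edgeR adjusted p = 0.00229), and GJB1, the gap junction protein connexin 32, fell by 7.12 (SE 0.70, adjusted p = 0.00318). FGB, the fibrinogen beta chain, had 1 count in HNF1B-KO and 2149 in HNF1B-WT, a ratio of 1785 (95% counting interval 320 to 70540), and APOH, a plasma glycoprotein, had 0, at least 40.7-fold lower. Of 20 pancreatic and foregut transcription factors, 1 rose and 6 fell over all genes, and 2 and 6 adjusted over the list alone. HNF1B, the targeted gene, was 1 of the 6 that fell, and it also entered the median and the camera test. For the list the median was -0.62 (camera adjusted p = 0.0283; adjusted p = 0.383 with an estimated correlation; adjusted p = 0.152 without HNF1B-KO C). ONECUT2, HNF4A and HNF4G, a paralog of HNF4A (-2.13, SE 0.37, adjusted p = 0.0151), were the falling members with the smallest p. HNF1A, the paralog of HNF1B, fell by 2.25 (SE 0.53, adjusted p = 0.0347), a call lost with any single library left out except HNF1B-KO C. SPDEF, a factor of secretory cells, rose by 0.79 (SE 0.20, adjusted p = 0.0413; 0.61, SE 0.20, adjusted p = 0.0885 after the regional subtraction), while FOXA2 (-0.31, adjusted p = 0.706) and GATA6 (0.40, adjusted p = 0.298) did not pass.

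Of the lipid synthesis lists, that of cholesterol synthesis had the most falling members in HNF1B-KO. Of 24 cholesterol synthesis genes, 0 rose and 14 fell over all genes, and 1 and 21 adjusted over the list alone. The list's median was -0.84 (camera adjusted p = 9.95e-10; adjusted p = 0.247 with an estimated correlation). INSIG1, an ER sterol sensor, fell from 66.8 ± 7.22 to 13.6 ± 2.62 CPM (-2.30, SE 0.19, edgeR adjusted p = 0.00195), HMGCS1, the HMG-CoA synthase, from 173 ± 10.9 to 61.2 ± 4.29 CPM (-1.50, SE 0.13, adjusted p = 0.00215), and SQLE, squalene epoxidase, by 1.69 (SE 0.17, adjusted p = 0.00343). Of 24 genes of fatty acid synthesis, 0 rose and 5 fell over all genes, and 0 and 6 adjusted over the list alone. Its members had a median of -0.30 (camera adjusted p = 0.0283; adjusted p = 0.402 with an estimated correlation). Fatty acid synthesis and desaturation in HNF1B-KO had an adjusted p of 0.0546 without HNF1B-WT A and 0.117 without HNF1B-KO C. FADS1, a fatty acid desaturase, fell by 1.71 (SE 0.15, adjusted p = 0.00215), FADS2 by 1.25 (SE 0.22, adjusted p = 0.0152) and FASN, fatty acid synthase, by 1.45 (SE 0.27, adjusted p = 0.0185).

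Inflammatory and interferon-stimulated genes passed camera in opposite directions. Of 26 NF-kB and inflammatory genes, 0 rose and 11 fell over all genes, and 0 and 12 adjusted over the list alone. Members had a median of -1.17 (camera adjusted p = 2.94e-05; adjusted p = 0.627 with an estimated correlation). The chemokine genes CXCL6 (-4.75, SE 0.25, edgeR adjusted p = 0.000395), CXCL2 (-3.40, SE 0.37, adjusted p = 0.00439) and CXCL5 (-4.91, SE 0.55, adjusted p = 0.00464) led the list, though CXCL2 has close copies that could share reads. Of 33 interferon-stimulated genes, 5 rose and 0 fell over all genes, and 8 and 1 adjusted over the list alone. For the list the median was 0.59 (camera adjusted p = 0.00195; adjusted p = 0.709 with an estimated correlation). OASL, an antiviral protein, rose by 2.30 (SE 0.37, adjusted p = 0.0128), STAT2, a transcription factor of interferon signalling, by 1.23 (SE 0.22, adjusted p = 0.0162) and HERC6 by 1.29 (SE 0.23, adjusted p = 0.0166). STAT2 lost the call once the regional shift was subtracted (0.74, SE 0.23, adjusted p = 0.0822).

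Of the 3 ER stress lists, the ATF4-CHOP list passed camera in HNF1B-KO. By camera on the interaction, the ATF4-CHOP list (adjusted p = 0.702) and the IRE1-XBP1 list (adjusted p = 0.222) did not differ detectably between the knockouts, and the ATF6 list stood higher in MYRF-KO (median difference 0.41, adjusted p = 0.0447; adjusted p = 0.531 with an estimated correlation). Of 21 ER chaperones of the ATF6 type, 1 rose and 1 fell over all genes and adjusted over the list alone (median 0.05 with a mean of -0.04, camera adjusted p = 0.972): HERPUD1 (0.62, SE 0.14, edgeR adjusted p = 0.0338) and SDF2L1 (-0.92, SE 0.21, adjusted p = 0.0334). Of 22 IRE1-XBP1 targets, 2 rose and 1 fell over all genes, and 4 and 1 adjusted over the list alone (median 0.13, camera adjusted p = 0.362): DERL1 (0.77, SE 0.15, adjusted p = 0.0224; 0.46, SE 0.10, adjusted p = 0.0282 after the regional subtraction), SEC31A (0.65, SE 0.16, adjusted p = 0.0391; 0.28, SE 0.11, adjusted p = 0.144 after the regional subtraction) and DERL3 (-4.27, SE 0.56, adjusted p = 0.00693). Of 27 genes of the ATF4-CHOP response, 6 rose and 1 fell over all genes and adjusted over the list alone (median 0.46, camera adjusted p = 0.0283; adjusted p = 0.709 with an estimated correlation; adjusted p = 0.111 without HNF1B-WT A and 0.101 without HNF1B-KO C). The rising members included ATF4 (0.72, SE 0.17, adjusted p = 0.0355; 0.48, SE 0.15, adjusted p = 0.0811 after the regional subtraction), the tryptophanyl-tRNA synthetase WARS1 (1.18, SE 0.15, adjusted p = 0.00702) and the serine synthesis enzyme PHGDH (1.26, SE 0.19, adjusted p = 0.00999), and DDIT4, an inhibitor of mTOR signalling, fell (-1.51, SE 0.35, adjusted p = 0.0331). HSPA5 (0.21, SE 0.15, adjusted p = 0.372), HSP90B1 (0.17, adjusted p = 0.403), DDIT3 (-0.06, adjusted p = 0.766) and XBP1 (-0.03, adjusted p = 0.916) did not pass. Of 21 genes of ER disulfide exchange, 1 rose and 4 fell over all genes, and 1 and 6 adjusted over the list alone (median -0.43, camera adjusted p = 0.0651), among them AGR2 (0.96, SE 0.21, adjusted p = 0.0279; 0.59, SE 0.23, adjusted p = 0.143 after the regional subtraction) and PRDX4, an ER peroxiredoxin (-1.48, SE 0.14, adjusted p = 0.00277; -0.72, SE 0.12, adjusted p = 0.0145 after the regional subtraction).

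The vesicle coat list passed camera in HNF1B-KO and the glycosylation lists did not. Of 34 COPII and COPI genes, 6 rose and 0 fell over all genes and adjusted over the list alone (median 0.27, camera adjusted p = 0.000970; adjusted p = 0.247 with an estimated correlation). CREB3L1, an ER-bound transcription factor of secretory genes, rose by 4.83 (SE 0.49, edgeR adjusted p = 0.00353), SEC24C by 0.63 (SE 0.12, adjusted p = 0.0174) and ARF4, a GTPase of vesicle budding, by 0.69 (SE 0.13, adjusted p = 0.0192). Of 26 O-glycosylation enzymes, 5 rose and 4 fell over all genes, and 10 and 5 adjusted over the list alone (median 0.22, camera adjusted p = 0.451), among them B4GALNT3 (3.26, SE 0.38, adjusted p = 0.00516) and GCNT3, a mucin core enzyme (-3.72, SE 0.47, adjusted p = 0.00624). Of 33 N-glycosylation genes, 0 rose and 2 fell over all genes and adjusted over the list alone (median -0.09, camera adjusted p = 0.489), KRTCAP2 (-0.91, SE 0.14, adjusted p = 0.0120) and MGAT3 (-2.64, SE 0.59, adjusted p = 0.0309). Of 21 genes of the CEACAM and glycoprotein list, 7 rose and 3 fell over all genes, and 10 and 4 adjusted over the list alone. The list's median was 0.71 (camera adjusted p = 0.137). CEACAM6 rose by 2.12 (SE 0.47, adjusted p = 0.0301; 1.63, SE 0.45, adjusted p = 0.0629 after the regional subtraction) and PLAT, the tissue plasminogen activator, by 2.64 (SE 0.38, adjusted p = 0.00919), while LCN2, an iron-binding secreted protein, fell by 2.60 (SE 0.52, adjusted p = 0.0224). Of 13 mucins and trefoil peptides, 0 rose and 2 fell over all genes and adjusted over the list alone (median -0.29, camera adjusted p = 0.451), among them TFF2 (-1.31, SE 0.32, adjusted p = 0.0381). MUC1 (-0.25, adjusted p = 0.454), MUC5AC (-0.29, adjusted p = 0.683), MUC5B (-2.17, adjusted p = 0.0726) and CEACAM5 (1.55, adjusted p = 0.0896) did not pass. After the regional subtraction MUC5B was called (-3.06, SE 0.55, adjusted p = 0.0167), and MUC5AC stood at -1.18 (SE 0.38, adjusted p = 0.0928).

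Among subtype markers, the basal-like list passed camera in HNF1B-KO and the classical list did not. Of 24 basal-like markers, 6 rose and 0 fell over all genes, and 8 and 3 adjusted over the list alone. Its members had a median of 0.92 (camera adjusted p = 0.0141; adjusted p = 0.613 with an estimated correlation; adjusted p = 0.0658 without HNF1B-KO C). Besides KRT17 these included KRT6A, a keratin with close copies (5.18, SE 0.61, edgeR adjusted p = 0.00524), and FAM83A (1.86, SE 0.25, adjusted p = 0.00717). Of 13 classical subtype markers, 2 rose and 3 fell over all genes, and 2 and 4 adjusted over the list alone. Members had a median of -0.97 (camera adjusted p = 0.111). ANXA10, an annexin of gastric-type epithelium, fell from 280 ± 170 to 6.53 ± 0.882 CPM (-5.42, SE 0.52, adjusted p = 0.00282). Of 25 epithelial genes, 3 rose and 1 fell over all genes, and 7 and 1 adjusted over the list alone. For the list the median was 0.54 (camera adjusted p = 0.0283; adjusted p = 0.709 with an estimated correlation). Epithelial adhesion and keratins in HNF1B-KO had an adjusted p of 0.134 without HNF1B-WT A and 0.0922 without HNF1B-WT C. Among its calls were ESRP1, an epithelial splicing factor (1.59, SE 0.30, adjusted p = 0.0194), and CLDN3 (-2.05, SE 0.34, adjusted p = 0.0134). Of 22 mesenchymal genes, 3 rose and 0 fell over all genes and adjusted over the list alone (median 0.09, camera adjusted p = 0.798), among them COL1A1, a chain of type I collagen (4.13, SE 0.64, adjusted p = 0.0114). COL1A1 in HNF1B-KO lost its call without HNF1B-WT A (adjusted p = 0.0596) and HNF1B-WT C (adjusted p = 0.0505). CDH1 (0.44, adjusted p = 0.290) and VIM (0.06, adjusted p = 0.873) did not pass. Of 25 basement membrane and integrin genes, 4 rose and 3 fell over all genes, and 5 and 3 adjusted over the list alone (median 0.14, camera adjusted p = 0.972), among them the integrin ITGB6 (2.20, SE 0.20, adjusted p = 0.00270) and the proteoglycan HSPG2 (-2.05, SE 0.16, adjusted p = 0.00154).

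The duct and lysosome lists passed camera in HNF1B-KO, though most of their members did not pass singly. Of 22 duct and cilium genes, 4 of whose list are also HNF1 targets, 2 rose and 4 fell over all genes, and 3 and 8 adjusted over the list alone. The list's median was -0.25 (camera adjusted p = 0.0490; adjusted p = 0.387 with an estimated correlation). Duct ion transport and cilium in HNF1B-KO lost the call without any single library except HNF1B-KO A (adjusted p = 0.0546 to 0.121). SLC4A4, a sodium bicarbonate cotransporter, fell from 43.9 ± 21.3 to 0.602 ± 0.510 CPM (-6.10, SE 0.72, edgeR adjusted p = 0.00526), and BICC1, an RNA-binding protein whose loss gives cystic kidneys, from 390 ± 61.7 to 36.9 ± 17.3 CPM (-3.40, SE 0.35, adjusted p = 0.00390). ANO1, a chloride channel, rose by 1.90 (SE 0.35, adjusted p = 0.0175). Of 27 lysosome and autophagy genes, 7 rose and 0 fell over all genes, and 10 and 1 adjusted over the list alone. Its members had a median of 0.27 (camera adjusted p = 0.0283; adjusted p = 0.684 with an estimated correlation). Lysosome and autophagy in HNF1B-KO had an adjusted p of 0.0894 without HNF1B-WT A and 0.230 without HNF1B-KO C. Rising members were CTSD, the protease cathepsin D (1.46, SE 0.21, adjusted p = 0.00994; 0.82, SE 0.32, adjusted p = 0.145 after the regional subtraction), and TFEB, a transcription factor of lysosomal genes (1.85, SE 0.28, adjusted p = 0.0106).

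The remaining lists did not pass camera in HNF1B-KO. Of 15 myelin genes, 2 rose and 3 fell over all genes, and 3 and 4 adjusted over the list alone (median 0.03 but lower by camera's sign, adjusted p = 0.911), among them GSN, the actin regulator gelsolin (1.81, SE 0.17, edgeR adjusted p = 0.00281). Of 30 cell cycle genes, 1 rose and 4 fell over all genes and adjusted over the list alone (median -0.03, camera adjusted p = 0.522), among them TOP2A (-1.08, SE 0.25, adjusted p = 0.0350; -0.61, SE 0.22, adjusted p = 0.119 after the regional subtraction). Of 26 hypoxia and glycolysis genes, 1 rose and 0 fell over all genes and adjusted over the list alone (median 0.04 with a mean of -0.08, camera adjusted p = 0.970), PKM, pyruvate kinase (1.05, SE 0.17, adjusted p = 0.0128). Of 20 p53 targets, 1 rose and 0 fell over all genes and adjusted over the list alone, DDB2 (0.95, SE 0.20, adjusted p = 0.0266; 0.26, SE 0.12, adjusted p = 0.185 after the regional subtraction; list median -0.03 but higher by camera's sign, adjusted p = 0.996). Of 38 ribosomal protein genes, 0 rose and 2 fell over all genes and adjusted over the list alone, RPL23 (-1.18, SE 0.16, adjusted p = 0.00881) and RPL19 (-0.85, SE 0.18, adjusted p = 0.0262), both on the shifted part of chromosome 17 (list median 0.06, camera adjusted p = 0.775). After the regional subtraction neither passed: RPL23 stood at -0.64 (SE 0.17, adjusted p = 0.0522) and RPL19 at -0.24 (SE 0.16, adjusted p = 0.350). Of 13 mitochondrially encoded mRNAs, 0 passed edgeR over all genes or adjusted over the list alone (median -0.25, camera adjusted p = 0.112).

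The lists for markers of other cell types did not pass camera in HNF1B-KO, though fry called the acinar (adjusted p = 0.0120) and leukocyte (adjusted p = 0.0178) lists lower. Of 7 acinar markers tested, 2 rose and 2 fell over all genes, and 2 and 3 adjusted over the list alone, with a median of -0.30 and a mean of 0.73 (camera adjusted p = 0.451). PRSS2 and PRSS1 rose, the latter from 3 to 554 counts (ratio 222, 95% counting interval 75.7 to 1081), SPINK1, a trypsin inhibitor, fell by 3.18 (SE 0.44, edgeR adjusted p = 0.00838), and CELA3A, an elastase, fell to 0 counts, at least 19.1-fold lower. Of 8 endocrine markers, 1 rose and 0 fell over all genes, and 1 and 1 adjusted over the list alone, SCG2, a granin of secretory granules, rising by 3.33 (SE 0.25, adjusted p = 0.00154; median 0.09, camera adjusted p = 0.522). Of 7 fibroblast and endothelial markers, 1 rose, COL1A1, and 1 fell, RGS5 (-1.59, SE 0.26, adjusted p = 0.0129), over all genes and adjusted over the list alone (median -0.39 with a mean of 0.06, camera adjusted p = 0.286). Of 6 leukocyte markers, 0 rose and 1 fell over all genes and adjusted over the list alone, LYZ, lysozyme, which the glycoprotein list also holds (-1.93, SE 0.25, adjusted p = 0.00642; median -0.15, camera adjusted p = 0.522).

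**Figure D2:**
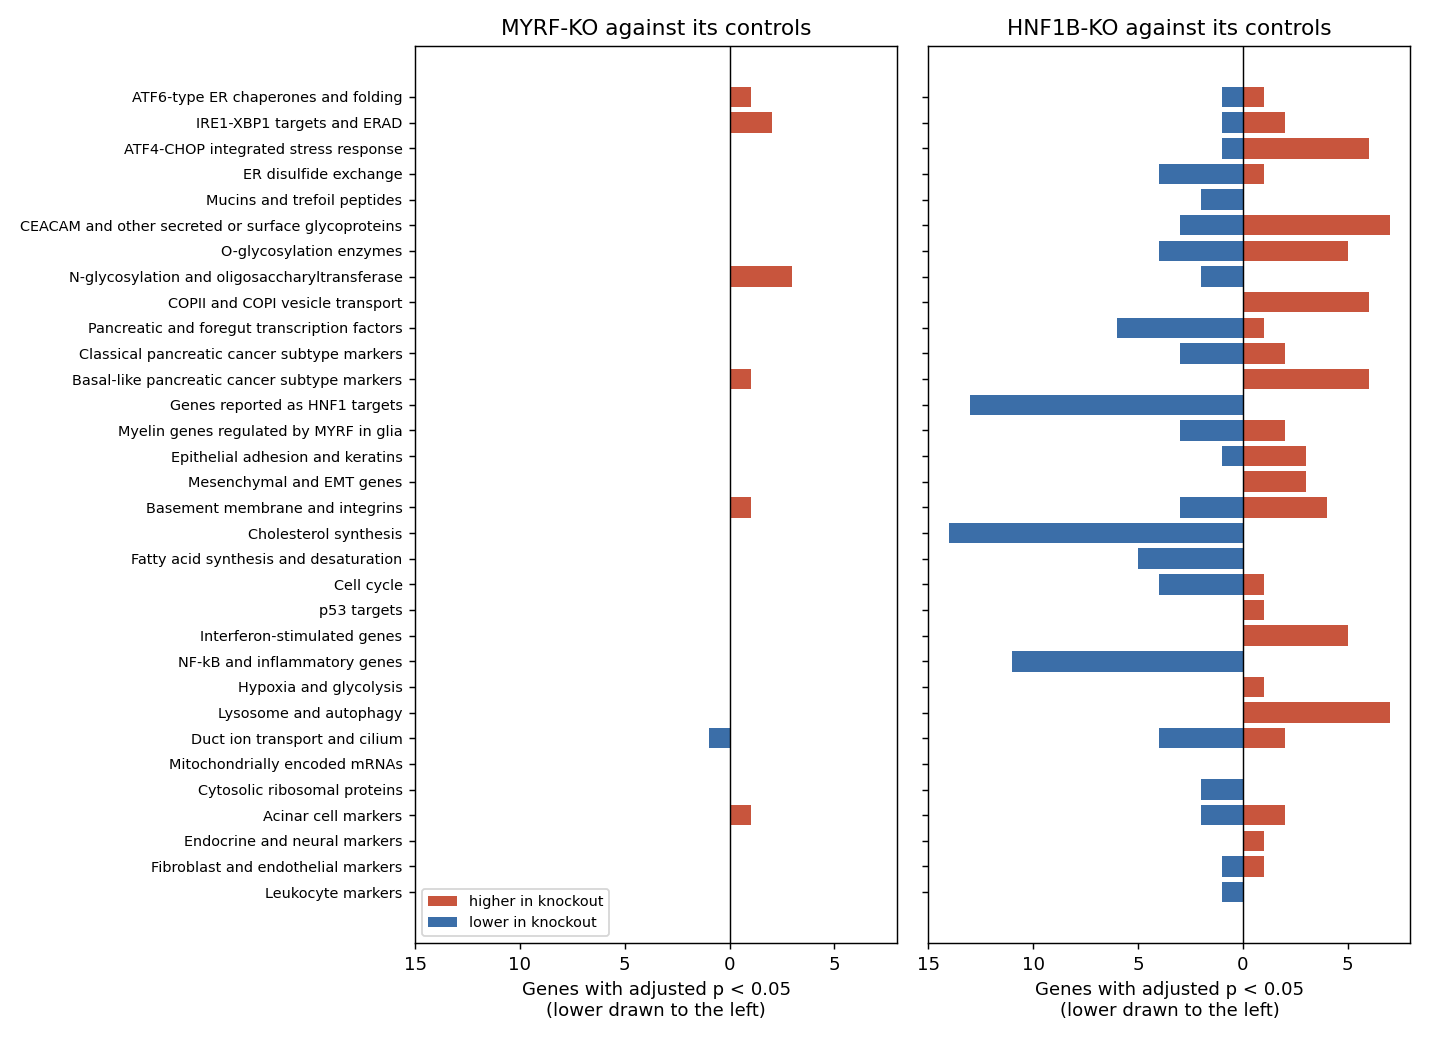
Number of members of each of the 32 gene lists with an edgeR adjusted p under 0.05 in MYRF-KO and in HNF1B-KO, higher to the right and lower to the left. In HNF1B-KO 14 of 24 cholesterol synthesis genes and 13 of 22 HNF1 targets were lower, and in MYRF-KO the highest number was 3, for N-glycosylation.

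Long runs of neighbouring genes shifted together in HNF1B-KO, and the segments named here were chosen after their values were seen. Over the 182 genes at 0 to 47 Mb of chromosome 11, the median log2 difference from the HNF1B-WT mean was 1.00, 1.12 and 0.21 in HNF1B-KO A, B and C, and 58 were called higher and 2 lower. Over the 137 genes at 36 to 47 Mb of chromosome 17, which holds HNF1B, it was -0.21, -0.59 and -0.51, with 37 called lower and 2 higher. Over the 35 genes at 0 to 15 Mb of chromosome 18 it was 1.06, 1.17 and 0.12, and over the 298 genes of chromosome 20 it was -0.46, -0.43 and 0.21. A control was shifted as well: over the 501 genes of chromosome 7 it was -0.16, 0.33 and -0.16 in HNF1B-WT A, B and C, and 0.14, 0.23 and -0.16 in HNF1B-KO A, B and C. On chromosomes 11, 18 and 20 HNF1B-KO A and B shifted alike and C did not, while on chromosome 17 B and C were closer. Whether A and B are related clones cannot be told from counts, and the tests took all libraries as independent. After the median shift of 50 neighbouring genes was subtracted in each library, 1730 genes passed, 1264 of them among the 2003. TM4SF4, ONECUT2, HNF4A, PKHD1, INSIG1, CXCL6, SLITRK6 and KRT17 stayed called, and HNF1B itself stood at -3.08 (SE 0.88, adjusted p = 0.0704).

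**Figure D3:**
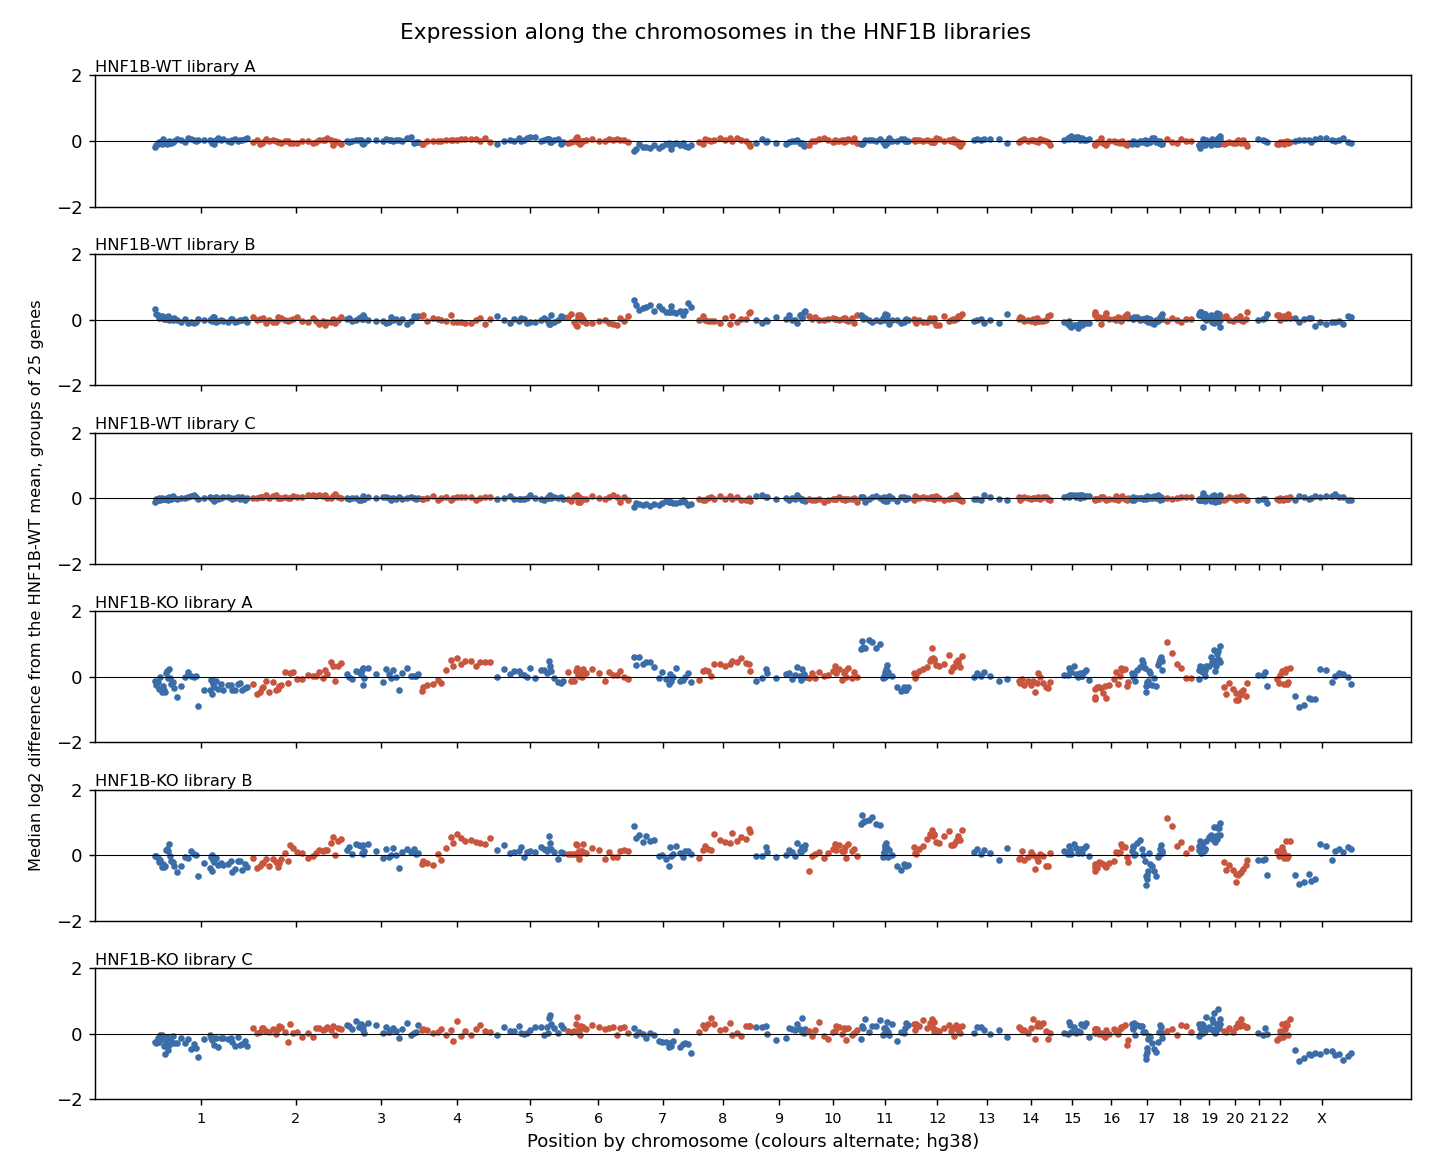
Median log2 difference from the HNF1B-WT mean for groups of 25 neighbouring genes along the chromosomes, for the 6 HNF1B libraries. The start of chromosome 11 lies near 1.00 and 1.12 in HNF1B-KO A and B over 182 genes and at 0.21 in HNF1B-KO C, and chromosome 20 lies below 0 in A and B and above 0 in C.

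The third comparison asked whether both knockouts changed the same genes, on 13074 genes tested in both, with separate control libraries. MYLK and CCN2 fell in both, MYLK by 1.98 in MYRF-KO (SE 0.24, edgeR adjusted p = 0.0379) and 2.37 in HNF1B-KO (SE 0.23, adjusted p = 0.00282), and CCN2 by 1.80 (SE 0.25, adjusted p = 0.0427) and 1.65 (SE 0.33, adjusted p = 0.0224). CYB5R2 (1.55 and 2.33), STX1A, a membrane fusion protein (1.23 and 1.14), AHNAK2 (0.91 and 1.52) and HERPUD1 (1.08 and 0.62) rose in both. GPX2 (1.72 and -4.90) and G0S2 (1.77 and -2.43) rose in MYRF-KO and fell in HNF1B-KO, and FBN2 (-2.0 and 1.78) and CPED1 (-3.75 and 3.33) did the reverse. In all, 6 genes rose in both against 3.24 for independent lists (Fisher's exact test, two-sided, p = 0.135, adjusted p = 0.180 over 4 tests), and 2 fell in both against 1.47 (p = 0.656, adjusted p = 0.656). Of 42 MYRF-KO rises, 7 were among the 833 HNF1B-KO falls, against 2.68 (Fisher's exact test, p = 0.0159, adjusted p = 0.0636). Of 23 MYRF-KO falls, 4 were among the 1008 HNF1B-KO rises, against 1.77 (Fisher's exact test, p = 0.0963, adjusted p = 0.180). No gene was shared in either direction without WT 1, WT 3 or MYRF-KO 3. Across genes, which are not independent replicates, the log2 fold changes did not correlate (Pearson r = -0.00815, Spearman rho = -0.00571).

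**Figure D4:**
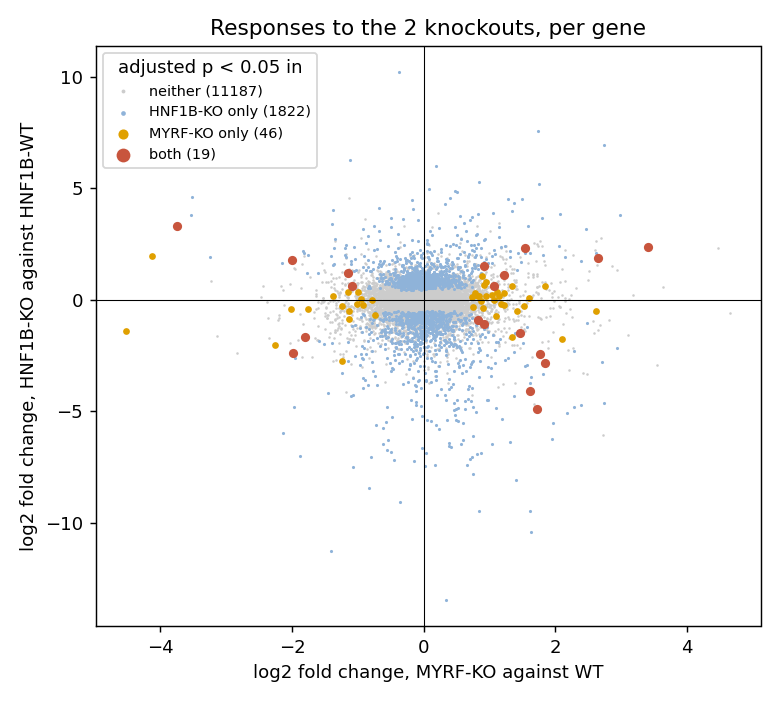
Log2 fold change of each gene in MYRF-KO (horizontal) against HNF1B-KO (vertical), coloured by edgeR calls. Of 13074 genes, 19 passed in both, 46 in MYRF-KO alone and 1822 in HNF1B-KO alone.

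The fourth comparison tested where the responses to the knockouts differed, as the MYRF-KO minus the HNF1B-KO log2 fold change, over 14521 genes. TM4SF4 differed by 9.93 (SE 0.88, edgeR adjusted p = 0.000195), with -1.39 in MYRF-KO and -11.32 in HNF1B-KO, and FBN2 by -3.72 (SE 0.36, adjusted p = 0.000169), with -1.99 and 1.73. COL1A1 differed by -4.77 (SE 0.82, adjusted p = 0.00595) and TUBA1A, an alpha tubulin with close copies, by -3.97 (SE 0.73, adjusted p = 0.00803), with -1.83 in MYRF-KO and 2.15 in HNF1B-KO. In all 1796 genes passed, 995 with the higher value in MYRF-KO and 801 with the lower. By camera 9 of 32 lists passed, and 2 of them also with an estimated correlation: the HNF1 targets, with a median difference of 3.15 (adjusted p = 5.98e-10; adjusted p = 0.0173 with an estimated correlation), and the pancreatic and foregut transcription factors, with 1.37 (adjusted p = 0.000217; adjusted p = 0.0306 with an estimated correlation). The foregut list holds HNF1B itself, the gene targeted in HNF1B-KO, so part of its difference was set by the design. It also shares 2 genes with the HNF1 targets, so these 2 lists are not independent. The count of differing genes was 3074 without HNF1B-KO C and 1025 without HNF1B-WT C.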

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

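The test of correlation between neighbouring genes, the subtraction of the regional shift and of the length trend, the regional test of the ribosomal genes, the segments named, and the criterion for a kept stress response were chosen only after the data were examined.

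The responses to the knockouts differed, by the test of the difference itself (edgeR, interaction), for 1796 genes. The differences of MYRF-KO minus HNF1B-KO, on the log2 scale, were 14.08 for HABP2 (adjusted p = 0.00803), 12.13 for FGB (adjusted p = 0.00359), 10.42 for TINAG (adjusted p = 0.00146), 9.93 for TM4SF4 (adjusted p = 0.000195) and 8.83 for SPP1 (adjusted p = 0.0362). They were -10.51 for KLK5 (adjusted p = 0.0219), -4.77 for COL1A1 (adjusted p = 0.00595), -3.97 for TUBA1A (adjusted p = 0.00803), -3.93 for CD38 (adjusted p = 0.0477) and -3.72 for FBN2 (adjusted p = 0.000169). HABP2, FGB and TINAG had 0, 1 and 1 counts in HNF1B-KO, so their fitted differences depend on the prior count and are no bounds. TINAG stood at 1143 counts in HNF1B-WT, a ratio of 950 (95% counting interval 170 to 37540). CD38 lost its call with any of the libraries left out except HNF1B-KO C, and SPP1 with any except MYRF-KO 2, MYRF-KO 3, HNF1B-WT B and HNF1B-KO C. KLK5 in the interaction lost its call without WT 2 (adjusted p = 0.0730), HNF1B-WT A (adjusted p = 0.0575) and HNF1B-WT C (adjusted p = 0.0613), with glmTreat (adjusted p = 0.0792) and with limma-voom (adjusted p = 0.578). With limma-voom HABP2 in the interaction (adjusted p = 0.0508) and FGB in the interaction (adjusted p = 0.0866) lost theirs too, as did SPP1 and CD38 there, with glmTreat and without a filter. The lists of foregut transcription factors and of HNF1 targets differed by medians of 1.37 and 3.15. The first list holds HNF1B itself and shares 2 genes with the second.

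Among 100 ways of splitting the libraries, the real split included, 1 gave as many differing genes as the real 1796, and the highest other gave 1020, which excludes chance only for the joint grouping of both experiments. The 8 draws that kept the HNF1B groups as labelled, the real one included, gave 506 to 1796, and the highest without them gave 5, so the count follows the HNF1B groups. These 8 draws are too few for a share under 0.05, so the count says nothing on chance for the MYRF groups within them. For the 9 lists of the interaction, 36 of the 100 splits gave as many, up to 15, so chance cannot be excluded. The 19 genes shared by both knockouts were matched by 1 of 100 pairs of splits, the real pair, with 0 in the highest other. No split other than the real one called a gene in either knockout, so the other pairs had nothing to share and this count of pairs says nothing about the overlap. Against independent lists no direction passed Fisher's exact test (adjusted p = 0.0636 to 0.656). For either knockout alone, the 6 libraries make 10 splits, too few for a share under 0.05. The real split gave 69 genes in MYRF-KO (highest other 0) and 2003 in HNF1B-KO (highest other 0), each matched by 1 split, itself. It gave 15 lists in MYRF-KO (highest other 10; 1 split) and 12 in HNF1B-KO (highest other 12; 2 splits).

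Genes along whole chromosome segments shifted together in HNF1B-KO. After the regional shift was subtracted 1730 genes were called, 1264 of them among the 2003 called before, which argues against copy-number differences between clones as the whole cause of the calls. As a contributor they stay a candidate explanation: a gene's log2 fold change correlated across genes with the median of genes 2 to 10 Mb away at 0.381, against at most 0.0431 in 1000 shuffles, although DNA would be needed to tell. Loss of HNF1B stays open as a cause of calls: after the subtraction the HNF1 target genes, among them FGB and PKHD1, kept a median of -3.74. As the shifts were removed first, that median cannot decide what shifted the segments. The segments differed between the knockout libraries, with chromosome 20 at -0.46, -0.43 and 0.21 in HNF1B-KO A, B and C.

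Cytosolic ribosomal protein genes stood higher in MYRF-KO, with a median log2 fold change of 0.448. The length available sums all annotated exons of a gene, so a bias with the length of the transcripts themselves stays open. The median was 0.420 after the trend with summed exon length was subtracted, which argues against that trend as the cause. The median was at least 0.383 with any library left out, which argues against a single library. After the regional shift was subtracted it was 0.4205, with a bootstrap interval of 0.857 to 1.13 for its ratio to the value before, which argues against copy-number differences between clones as the whole cause. That interval resampled genes as if independent, so it holds no spread between clones. Loss of MYRF stays open, and may not be the only explanation, since other differences between clones were not tested.

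Genes of the unfolded protein and integrated stress responses, 69 in all, stood higher in MYRF-KO, with a median of 0.367. A bias with transcript length stays open here too. The median was 0.356 after the trend with summed exon length was subtracted and at least 0.311 with any library left out, which argues against that trend and against a single library as the cause. After the regional shift was subtracted it was 0.279, and the bootstrap interval of its ratio to the value before, 0.636 to 1.36, was too wide to tell, so copy-number differences could account for part. This interval too resampled genes as if independent and holds no spread between clones. Loss of MYRF stays open.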

How the results depend on the processing

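The likelihood ratio test, the subtraction of the regional shift, the subtraction of the length trend and the block within the overlap were chosen only after the data were examined. The other settings were fixed before. No named gene or list whose call passed changed sign under any setting run.

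For MYRF-KO against WT, the 69 calls became 949 with DESeq2, 731 with the likelihood ratio test, 131 without a filter, 35 after the regional subtraction and 0 with glmTreat against a 2-fold change, while 2581 genes had an unadjusted p under 0.05. Leaving out 1 library gave 0 to 98 calls: 0 without WT 1, WT 3 or MYRF-KO 3, 4 without WT 2, 37 without MYRF-KO 2 and 98 without MYRF-KO 1 (38 higher, 60 lower). Fewer libraries lower the power of the test, but the cause of the differences between libraries was not tested. With the replicate number as a block the count was 78 (41 higher, 37 lower), of which 39 were among the 69. Same-numbered libraries deviated from their group means with correlations of 0.106, 0.00236 and 0.129 across genes, and WT 1 correlated best with MYRF-KO 2, so the numbers did not pair the libraries. The block in the MYRF-KO fit alone left 11 genes shared in the same direction and 9 in opposite directions. No paired analysis was possible for HNF1B-KO or the interaction because the HNF1B columns carry no replicate number.

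For HNF1B-KO, the 2003 calls became 3414 with DESeq2, 3160 with a dispersion shared by 12 libraries, and 218 with glmTreat, which also asks for over 2-fold. Leaving out 1 library gave 376 to 4503: 376 without HNF1B-WT A, 977 without HNF1B-WT B, 436 without HNF1B-WT C, 801 without HNF1B-KO A, 524 without HNF1B-KO B and 4503 without HNF1B-KO C. The higher count without HNF1B-KO C goes with its distance from the other knockout libraries. It rests on HNF1B-KO A and B, which shared regional shifts that C did not and may not be independent. The interaction's 1796 calls became 240 with glmTreat and 1025 to 3074 with 1 library left out (1109 without WT 1, 1097 without WT 3, 1183 without MYRF-KO 3, 1097 without HNF1B-WT A, 1025 without HNF1B-WT C, 1046 without HNF1B-KO B and 3074 without HNF1B-KO C). Genes shared in the same direction, 8, became 142 with DESeq2, 13 without a filter, 0 with glmTreat and 0 to 17 with 1 library left out (0 without WT 1, WT 3 or MYRF-KO 3, 1 without WT 2, HNF1B-WT A or HNF1B-KO B, 3 without HNF1B-WT B or HNF1B-KO A, 5 without HNF1B-WT C, 14 without MYRF-KO 1 and 17 without HNF1B-KO C). Those in opposite directions, 11, became 132, 12, 0 and 0 to 12 (0 without WT 1, WT 3 or MYRF-KO 3, 1 without WT 2, 3 without HNF1B-WT A, 4 without HNF1B-KO B, 5 without HNF1B-WT B or C, 6 without HNF1B-KO A and 7 without MYRF-KO 2). Their correlation across genes stayed between -0.0525 and 0.0179.

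With an estimated correlation, camera called 0 of the 32 lists in each knockout comparison, against 15 and 12 with the preset one, and fry called 3 and 9. Leaving out 1 library gave 11 to 16 lists in MYRF-KO and 6 to 14 in HNF1B-KO (7 without HNF1B-WT A and 6 without HNF1B-KO C). Of 28 named genes called in MYRF-KO, 0 passed under every setting. Of 121 in HNF1B-KO, 35 did, among them TM4SF4, ONECUT2, HNF4A, PKHD1, CXCL6, INSIG1, SLITRK6 and KRT17, and of 10 in the interaction, 5 did (COL1A1, FBN2, TINAG, TM4SF4 and TUBA1A). Except where stated, the causes were not tested. Depth limits low genes most: FGB and TINAG each rested on 1 read in HNF1B-KO, and CFTR, with 0 to 10 reads per library, could not be tested. In the HNF1B design 19.6% of the simulated 2-fold changes were recovered, with 97 genes changed 2-fold and 99 changed 4-fold. The real comparison called 2003 genes, down to a log2 fold change of 0.43 in size. As the Benjamini-Hochberg adjustment depends on the number of changed genes, 19.6% does not give the power there. A missing call is still no evidence of an unchanged gene.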

Other observations

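The HLA class II genes and the correlation test below were chosen after the data were examined.

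Of 13 genes of antigen presentation by HLA class II tested in HNF1B-KO (the HLA-D genes, CD74 and CIITA), 0 rose, 12 fell and 1 did not pass, and no list test was run on them. HLA-DPA1, an alpha chain on chromosome 6, fell from 181 ± 13.2 to 4.73 ± 1.69 CPM (SD, n = 3; log2 fold change -5.25, SE 0.30, edgeR adjusted p = 0.000657). HLA-DRA fell by 4.78 (SE 0.65, adjusted p = 0.00829) and HLA-DRB1 fell by 5.48 (SE 0.83, adjusted p = 0.0106). CD74, the invariant chain on chromosome 5, fell by 2.21 (SE 0.29, adjusted p = 0.00659), and CIITA, the class II transactivator on chromosome 16, by 1.78 (SE 0.24, adjusted p = 0.00717). HLA-DOB did not pass (log2 fold change -0.34, SE 0.31, adjusted p = 0.499). In MYRF-KO none of these genes passed the edgeR test: HLA-DRA stood at -0.56 (SE 0.31, adjusted p = 0.383) and CIITA at -0.77 (SE 0.20, adjusted p = 0.103). Class II genes are polymorphic paralogs, so reads could be split between them, but CD74 and CIITA are single genes. The cause was not tested.

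Across the genes of MYRF-KO, those in the shortest 10% by exon length had a median log2 fold change of 0.145, while the medians of the other 9 groups of 10% lay between -0.0328 and 0.0278.

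A hypothesis of this re-analysis was that the lower MYRF transcript in HNF1B-KO may carry the MYRF-KO changes into those cells. Over the 65 genes called in MYRF-KO and tested in both, the log2 fold changes of the 2 comparisons correlated across genes with Pearson r = -0.065 (bootstrap 95% interval -0.371 to 0.28), and 37 had the same sign. Genes are not independent replicates. The interval's upper end, 0.28, lay under the 0.3 set for the test after the data were examined. That interval treats genes as independent, and changes in HNF1B-KO that do not come from MYRF would also enter r. The test therefore cannot decide on such a carry-over. The MYRF transcript was lowered in HNF1B-KO and not removed, and a change in the encoded protein of MYRF-KO may act differently, so a link stays open.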
